A study of Homo sapiens with 28 samples.

How the data were processed

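RNA of 28 libraries of MDA-MB-231 cells was profiled by sequencing. Per the labels, RNA was extracted with an RNeasy kit, messenger RNA was taken with poly-T beads, and libraries were made with random hexamer primers by a commercial provider. The authors deposited a table of counts per gene, whose values are whole numbers, and a table of FPKM values for the same genes and libraries. Per the submitters' processing notes the genome build was hg38 and DESeq2 was used, with no role stated; the aligner and the counting tool are not given in the sources used here. The deposited FPKM values, checked against the deposited counts for genes with a count of at least 50, equalled count per gene length per scaled library total, with a relative deviation of at most 5.3e-15, and the scaled totals were 0.856 to 1.08 times the count totals. All 58735 gene identifiers and coordinates matched GENCODE release 29; 23006 genes had a count of 0 in every library. Counts are per gene, so Tpm2.1 was not told apart from other products of TPM2. Each of the 28 columns was matched to its sample by the library name in the labels, and the gene description and transcription factor family columns were not used.

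Groups were taken from the labels: attached EV and Tpm2.1 cells, and EV, Tpm2.1 non-apoptotic and Tpm2.1 apoptotic cells at 4 times in suspension, 2 libraries each. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr on the groups, a mean per group over all 28 libraries), which tested 17191 genes with 14 residual degrees of freedom and a prior of 23. The common biological coefficient of variation was 4.77%. The standard error given with a log2 fold change is its absolute value over the square root of the F statistic, an approximation. Adjusted p values are Benjamini-Hochberg values within a contrast, and a gene passed at 0.05; a change past 2-fold is a passing gene with an absolute log2 fold change above 1. The 26 contrasts were the lines in attached cells, suspension against attached cells in either line, the fractions, each fraction against EV, 4 days against 5 hours, the change of the fraction difference over time and the difference of the line difference between suspension and attached cells; means over times weight the times equally.

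Gene lists, 32 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) in the 6 main contrasts, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 192 tests (over 32 for the fractions without 4 days); an estimated correlation per list and fry were run beside it. Some genes belong to more than 1 list. The genes named were TPM2, EPHA2, AKT1, AKT2, CDH1 and CDH2, the 6 highest and 6 lowest passing protein-coding genes with a mean of at least 10 CPM in a group and the same direction at every time, and, from each list that passed and from the adhesion, Eph, PI3K and AKT and both apoptosis lists, the 4 members with the smallest p and at least 1 CPM in a group; for genes shared by both fractions against EV, the 3 highest and 3 lowest. Some genes chosen in this way are not named in the text. CDH1 and CDH2, with 0 to 7 and 0 to 8 counts per library, were below the filter and not tested. Groups, contrasts, lists, this rule and the first set of alternatives were fixed before the data were examined.

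The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, protein-coding genes alone, the libraries of a contrast alone, the replicate number as a block, each library left out in turn, a GC correction (a lowess trend with span 0.2 on the GC content of the longest transcript, for 17183 genes, removed as an offset), the scaling of the FPKM table, means without 4 days, and lists after the GC correction. Where a group was left with 1 library, that library was assumed to vary like the other groups. For the 3 means with 16 libraries, 30 splits within each time, the real one included, were counted with a fixed seed. Totals of 13043529 to 27416335 counts per library limit low-count genes. The fits were tested on simulated data with 16413 genes tested: in attached cells 92.5%, 97% and 100% of genes changed 1.5, 2 and 4-fold were called and 4.5% of calls were false. In the mean of the fractions 100% were called at each size and 5.2% of calls were false. The changed genes were few and were drawn from well-counted genes only. These rates need not hold for genes near the filter or where many genes differ. With 16429 genes tested, simulated GC trends gave 4441 false genes past 2-fold before the correction and 2 after it. Of the changed genes 93% were still called. The simulated trends followed the same GC values that the correction used, so GC effects of another form were not tested. With 2 libraries per group, the p values reflect the spread between these libraries pooled over the groups.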

Results

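MDA-MB-231, a human triple-negative breast cancer line, was sequenced as a control line carrying an empty vector (EV) and as a line that overexpressed tropomyosin 2.1 (Tpm2.1), an actin-binding protein encoded by the gene TPM2. Cells were attached for 6 hours or held in suspension for 5 hours or for 1, 2 or 4 days, a setting in which cells can undergo anoikis, the apoptosis that follows loss of attachment. Suspended Tpm2.1 cells were parted on beads carrying Annexin V, a protein that binds phosphatidylserine on the surface of dying cells, which gave an apoptotic and a non-apoptotic fraction at each time. No separation is stated for EV cells or for attached cells, so line and separation changed together wherever the lines were compared in suspension. The series title names AKT, the receptor EphA2 and cell-cell adhesion as its subjects.

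The 28 libraries formed 14 groups of 2. The titles call the 2 libraries of a group biological replicates and do not say how their cultures were set apart. Gene counts summed to between 13043529 and 27416335 per library, with 23561107 to 27416335 in the attached groups and 13214201 and 13043529 in the apoptotic fraction at 4 days. That fraction had 18430 ± 349 genes with a count (SD, n = 2), against group means of 21520 to 24190 elsewhere, and on the first principal component (41.5% of the variance) its libraries lay at 193 and 189.9 while the others lay between -52.3 and 33.8. Fold changes below are log2 values with the standard error (SE) implied by the F test. Levels are counts scaled to library size (CPM) with the SD, and 17191 genes were tested.

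The first comparison set attached Tpm2.1 cells against attached EV cells. Only a single line of each kind is described, so Tpm2.1 overexpression cannot be told apart from other differences between the lines. TPM2 (ENSG00000198467, hg38 chromosome 9, 35681992 to 35690121) stood at 24.9 ± 3.22 CPM in EV cells and at 3302 ± 84.1 CPM in Tpm2.1 cells (SD, n = 2), a log2 fold change of 7.05 ± 0.098 (SE; adjusted p = 3.86e-37). MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160), a collagenase, rose from 130 to 1684 CPM, by 3.70 ± 0.078. NGFR, the low-affinity neurotrophin receptor, rose by 2.64 ± 0.3, the antiviral gene IFIT1 by 2.62 ± 0.1 and the endothelial receptor kinase TIE1 by 2.55 ± 0.082. SPNS2, a transporter of sphingosine-1-phosphate, fell by 1.99 and IL13RA2, a decoy receptor for interleukin 13, fell by 1.76.

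Interferon-stimulated genes were higher as a list in attached Tpm2.1 cells. Of 30 genes 18 rose and 1 fell (21 and 2 adjusted over the list alone), with a median of 0.92 (adjusted p = 5.55e-15) and with IFIT2 at 2.39 and OASL at 2.08. Of 26 NF-kB and inflammatory genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 1.16e-12). Among them were PTGS2, which makes prostaglandins, at 2.06, and IL1B, the cytokine interleukin 1 beta, at 1.25 ± 0.093. Immediate early genes rose in 14 of 24 cases with 1 fall (17 and 1 adjusted over the list alone, adjusted p = 2.47e-06), with EGR1 at 1.07 and KLF4 at 0.52. Of 10 endothelial markers listed 5 passed the count filter and were tested. Of these 2 rose (3 adjusted over the list alone, adjusted p = 0.0024), TIE1 and ESAM. Cholesterol synthesis genes fell in 21 of 26 cases and rose in 0 (the same adjusted over the list alone), as for FDFT1 at -0.63. Adjusted p was 1.74e-14 for this list, and adjusted p = 0.15 with an estimated correlation.

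Stress genes also moved in attached cells, in calls that an estimated correlation did not keep. Heat shock genes rose in 10 of 16 cases (11 adjusted over the list alone), with BAG3 at 0.39. Adjusted p was 5.08e-04, and adjusted p = 0.365 with an estimated correlation. Unfolded protein and integrated stress response genes rose in 11 of 26 cases and fell in 1 (12 and 1 adjusted over the list alone), with DDIT4 at 1.20 and HERPUD1 at 0.89. Adjusted p was 0.0026, and adjusted p = 0.32 with an estimated correlation. Mesenchymal genes rose in 4 of 13 cases and fell in 1 (5 and 1 adjusted over the list alone). Adjusted p was 0.0074, and adjusted p = 0.188 with an estimated correlation. Within that list the matrix protease MMP3 rose by 1.81 while the transcription factor SNAI2 fell by 0.63.

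Autophagy and lysosome genes fell in 11 of 26 cases and rose in 1 in attached Tpm2.1 cells (12 and 1 adjusted over the list alone). Adjusted p was 7.70e-05, and adjusted p = 0.198 with an estimated correlation. Ribosomal protein genes fell in 14 of 40 cases and rose in 1 (18 and 1 adjusted over the list alone). Adjusted p was 5.13e-06, and adjusted p = 0.376 with an estimated correlation. G1/S genes fell in 7 of 30 cases and rose in 2 (10 and 2 adjusted over the list alone). Adjusted p was 0.0481, and adjusted p = 0.407 with an estimated correlation. As signs of RNA quality, 11 of 13 mitochondrial mRNAs rose alongside these groups (11 adjusted over the list alone), with MT-ND4 at 0.64. Adjusted p was 0.0011, and adjusted p = 0.482 with an estimated correlation. So did 5 of 9 nuclear-retained RNAs (5, with 1 fall, adjusted over the list alone), with MALAT1 at 1.26. Adjusted p was 0.0046, and adjusted p = 0.34 with an estimated correlation. Mitochondrial mRNAs made up 1.61% ± 0.0283 of counts in EV and 2.16% ± 0.0283 in Tpm2.1 attached cells (SD, n = 2).

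EPHA2, AKT1 and AKT2 moved little in attached cells, while adhesion genes went both ways. EPHA2 (ENSG00000142627, chromosome 1, 16124337 to 16156087) stood at 697 ± 0.853 CPM in EV and 755.5 ± 3 CPM in Tpm2.1 cells (SD, n = 2). The difference of 0.12 ± 0.051 did not pass (adjusted p = 0.105), though it did among protein-coding genes alone, after a GC correction and with the attached libraries alone. AKT1 (ENSG00000142208, chromosome 14, 104769349 to 104795751) differed by -0.03 and AKT2 by -0.15, neither of which passed. Of 29 cell-cell adhesion genes 11 rose and 5 fell (11 and 6 adjusted over the list alone, adjusted p = 0.547), with the tight junction gene CLDN4 at 2.23 and the adhesion molecule L1CAM at -1.12. BIRC3 (ENSG00000023445, chromosome 11, 102317450 to 102339403), an inhibitor of apoptosis, rose by 2.05 ± 0.097. The pro-apoptotic BBC3 and PMAIP1 rose by 0.98 and 0.66 while BAX fell by 0.32.

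Pro-apoptotic genes rose in 3 of 12 cases and fell in 2 in attached Tpm2.1 cells (4 and 3 adjusted over the list alone, adjusted p = 0.567). Anti-apoptotic genes rose in 2 of 9 and fell in 1 (3 and 1 adjusted over the list alone, adjusted p = 0.0804). Over all genes 3516 passed, 1788 higher and 1728 lower in Tpm2.1 cells, 465 of them past 2-fold, and after the GC correction 2156 were higher and 1508 lower. Each of the 4 attached libraries, EV replicates 1 and 2 and Tpm2.1 replicates 1 and 2, moved that count by more than 1.5 times when left out, to between 2028 and 2188. Each such removal left a group with 1 library, which lowers power whichever library is left out. A fit of the 4 attached libraries alone called 5440.

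**Figure D1:**
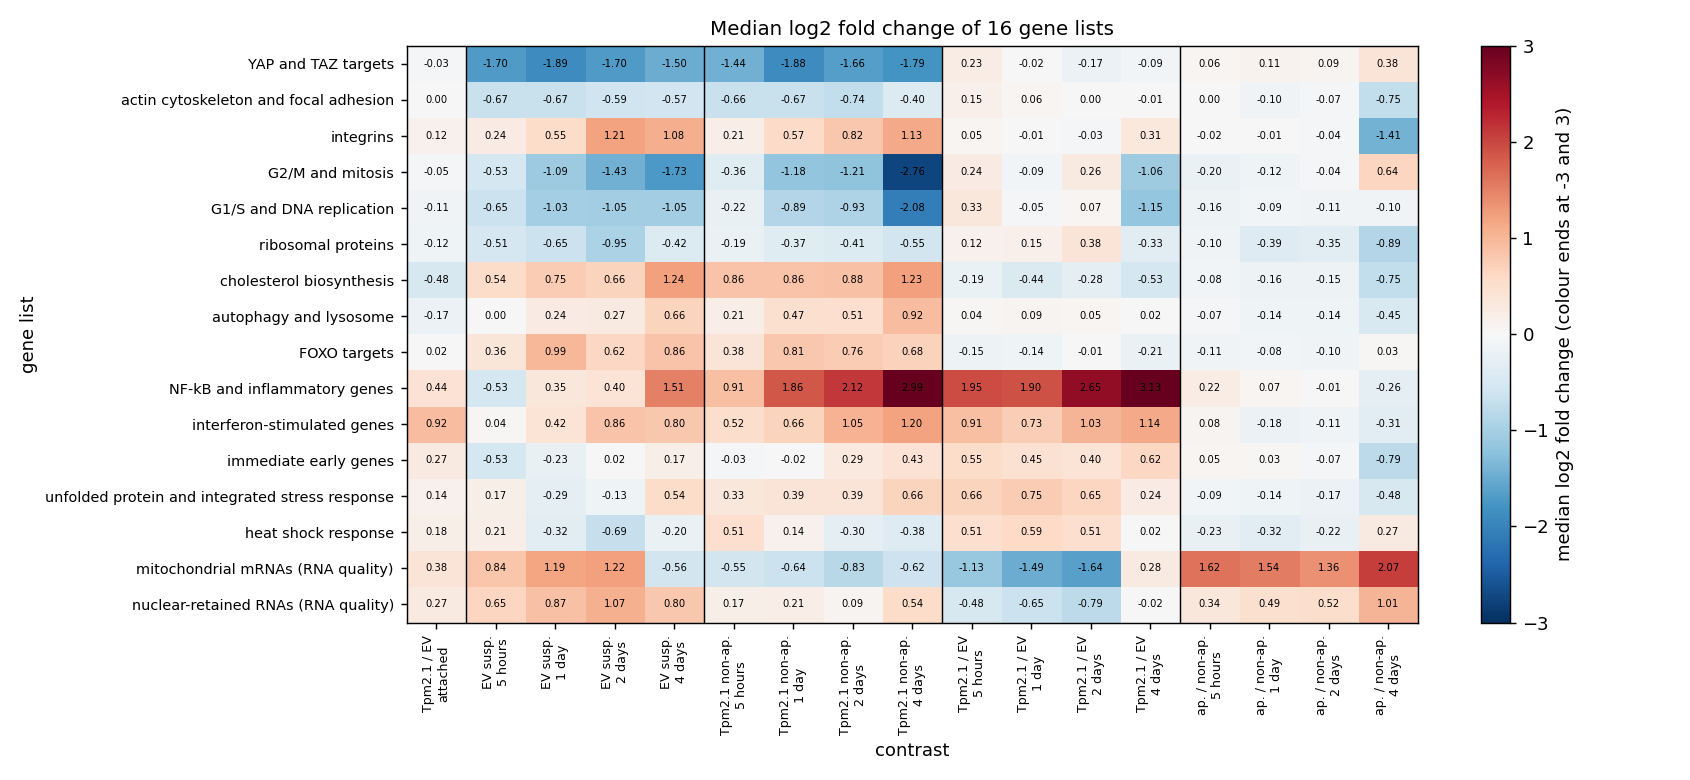
Heat map of the median log2 fold change of 16 gene lists (vertical) in 17 comparisons (horizontal), with red higher and blue lower in the first-named group. YAP and TAZ targets and G2/M genes were lower in suspension in both lines, and NF-kB and inflammatory genes had medians of 1.90 to 3.13 in non-apoptotic Tpm2.1 cells against EV at the 4 times.

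The second comparison set suspended EV cells, as the mean of 4 times (8 libraries), against attached EV cells (2 libraries). In either line attached cells were taken at 6 hours only, so at the later times suspension and time in culture changed together. Library names also number the attached libraries apart from the suspended ones. A difference in preparation could not be told apart from suspension. CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373), a secreted matrix protein and a known YAP target, fell from 1553 ± 16.4 CPM to 60.1, 54.5, 103 and 111 CPM at the successive times. Its mean log2 fold change was -4.31 ± 0.051 (SE, adjusted p = 1.56e-39), and CYR61 and ANKRD1 fell by 4.05 and 4.03. ITGA2 (ENSG00000164171, chromosome 5, 52989326 to 53094779), a collagen-binding integrin chain, rose from 95.7 CPM to between 771 and 877 CPM, by 3.10 ± 0.059. ITGA10 went from 1.53 CPM to 227 CPM at 2 days. BMF (ENSG00000104081, chromosome 15, 40087890 to 40108892), a pro-apoptotic BH3-only gene tied to detachment, rose from 3.26 CPM to 33.4, 44.6, 42.8 and 80.5 CPM, by 3.87 ± 0.1 (adjusted p = 7.69e-29). EPHA2 fell by 0.54 ± 0.039 in the mean, by 1.75 at 5 hours and by 0.61 at 1 day. At 2 days its difference was 0.00 and did not pass, and at 4 days it rose by 0.21.

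YAP and TAZ targets fell in 20 of 22 cases and rose in 1 in suspended EV cells (20 and 1 adjusted over the list alone), with a median of -1.72 (adjusted p = 7.57e-12). All 30 G2/M genes tested fell (30 adjusted over the list alone, adjusted p = 1.19e-17), with a median of -1.21 and CDC20 at -1.87. So did all 30 G1/S and replication genes (30 adjusted over the list alone, adjusted p = 4.42e-14), with a median of -0.91 and the nucleotide synthesis gene RRM2 at -1.64. Actin and focal adhesion genes fell in 30 of 35 cases and rose in 2 (30 and 3 adjusted over the list alone, adjusted p = 4.92e-09), with TAGLN at -3.12 and ACTN4 at -1.06. Integrins rose in 11 of 15 and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0018), with ITGB4 at 3.19 and ITGA1 at 1.52.

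FOXO targets rose in 16 of 20 cases and fell in 3 in suspended EV cells (16 and 3 adjusted over the list alone). Adjusted p was 0.0023, and adjusted p = 0.188 with an estimated correlation. Within the list the cyclin gene CCNG2 rose by 1.94 and the stress gene GADD45B fell by 2.45. Cholesterol synthesis genes rose in 21 of 26 cases and fell in 1 (21 and 1 adjusted over the list alone), with HMGCS1 at 1.88. Adjusted p was 2.47e-06, and adjusted p = 0.31 with an estimated correlation. Autophagy and lysosome genes rose in 20 of 26 and fell in 1 (20 and 1 adjusted over the list alone), with CTSD at 1.73. Adjusted p was 9.85e-05, and adjusted p = 0.198 with an estimated correlation. Interferon-stimulated genes rose in 18 of 30 cases and fell in 3 (18 and 3 adjusted over the list alone). Adjusted p was 0.0090, and adjusted p = 0.251 with an estimated correlation.

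Ribosomal protein genes fell in 38 of 40 cases and rose in 1 in suspended EV cells (38 and 1 adjusted over the list alone), with RPS2 at -1.24. Adjusted p was 2.40e-13, and adjusted p = 0.198 with an estimated correlation. All 13 mitochondrial mRNAs rose in the mean of the same libraries (13 adjusted over the list alone), with MT-ND4 at 1.07. Adjusted p was 0.0040, and adjusted p = 0.533 with an estimated correlation. Of 9 nuclear-retained RNAs 8 rose (8 adjusted over the list alone), with MALAT1 at 2.74. Adjusted p was 3.95e-04, and adjusted p = 0.253 with an estimated correlation. The share of counts on mitochondrial mRNAs was 3.14% ± 0.0566 at 5 hours, 4.23% ± 0.191 at 1 day, 3.98% ± 0.00707 at 2 days and 1.20% ± 0.113 at 4 days (SD, n = 2), with all 13 higher than in attached cells at 1 and 2 days and 10 lower at 4 days.

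The pro-apoptotic list did not pass in suspended EV cells, with 4 of 12 higher and 7 lower (the same adjusted over the list alone, adjusted p = 0.607). Its median of -0.23 and mean of 0.16 differed in sign, as BMF rose far while PMAIP1 and BID fell by 0.60 and 0.66. Anti-apoptotic genes rose in 3 of 9 cases and fell in 5 (the same adjusted over the list alone, adjusted p = 0.267), with MCL1 at -0.45. Cell-cell adhesion genes rose in 8 of 29 cases and fell in 13 (the same adjusted over the list alone, adjusted p = 0.303), with PKP2 at -1.25 and ALCAM at -0.65. PI3K and AKT pathway genes rose in 8 of 24 and fell in 7 (the same adjusted over the list alone, adjusted p = 0.863), with RICTOR at 1.02, and AKT1 fell by 0.34. In all 11403 genes passed in the mean, 5875 higher and 5528 lower, 3424 past 2-fold. The single times gave 9399, 10832, 11113 and 10231.

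The third comparison put the non-apoptotic Tpm2.1 fraction in suspension (8 libraries) against attached Tpm2.1 cells (2 libraries). No separation is stated for the attached cells, so suspension and separation changed together here. IL1B (ENSG00000125538, chromosome 2, 112829751 to 112836903) rose from 52.8 ± 1.72 CPM to 130, 1091, 1013 and 5862 CPM, a mean log2 fold change of 4.18 ± 0.078 (SE; adjusted p = 2.61e-33). PTGS2 rose by 5.31 ± 0.12, MMP3 by 4.60, and SPP1 (chromosome 4, 87975650 to 87983426), the secreted protein osteopontin, by 6.44 ± 0.32. CTGF fell by 3.80 ± 0.051, THBS1, a matrix glycoprotein, by 3.26, and TGFB2 by 3.39. BMF rose by 2.70 ± 0.1, the anti-apoptotic BCL2A1 and BIRC3 rose by 1.55 and 1.47, and BCL2 fell by 1.15. EPHA2 fell by 0.50 ± 0.039 in the mean, by 1.19 at 5 hours, 0.42 at 1 day and 0.35 at 2 days, and its difference of -0.05 at 4 days did not pass.

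In this fraction 22 of 26 NF-kB and inflammatory genes rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.99 (adjusted p = 1.85e-11), CXCL8 at 3.51 and CSF3 at 3.55. The same list in suspended EV cells had 13 rises and 4 falls (13 and 4 adjusted over the list alone), with a median of 0.44, and did not pass (adjusted p = 0.0530). Interferon-stimulated genes rose in 26 of 30 cases (26 adjusted over the list alone, adjusted p = 9.64e-08), with STAT2 at 1.40. YAP and TAZ targets fell in 21 of 22 cases and rose in 1 (21 and 1 adjusted over the list alone), with a median of -1.70 (adjusted p = 4.39e-14). All 30 G2/M genes fell (30 adjusted over the list alone, adjusted p = 1.08e-20), with a median of -1.35 and MKI67 at -1.78, and 29 of 30 G1/S genes fell (29 adjusted over the list alone, adjusted p = 1.33e-16). Actin and focal adhesion genes fell in 27 of 35 cases and rose in 4 (29 and 4 adjusted over the list alone, adjusted p = 3.00e-09), with the myosin heavy chain MYH9 at -1.15. Integrins rose in 12 of 15 and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 9.96e-04), with ITGA5 at 0.74.

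Several metabolic and stress lists rose in the non-apoptotic fraction with calls that an estimated correlation did not keep. Autophagy and lysosome genes rose in 23 of 26 cases (24 adjusted over the list alone), with GABARAPL1 at 2.11. Adjusted p was 5.57e-09, and adjusted p = 0.0586 with an estimated correlation. Cholesterol synthesis genes rose in 23 of 26 (23, with 1 fall, adjusted over the list alone), with INSIG1 at 1.70. Adjusted p was 2.62e-08, and adjusted p = 0.253 with an estimated correlation. Hypoxia and glycolysis genes rose in 19 of 30 cases and fell in 9 (19 and 9 adjusted over the list alone), with the angiogenic factor VEGFA at 2.05. Adjusted p was 0.0083, and adjusted p = 0.42 with an estimated correlation. FOXO targets rose in 13 of 20 cases and fell in 3 (15 and 3 adjusted over the list alone). Adjusted p was 0.0043, and adjusted p = 0.198 with an estimated correlation. Mesenchymal genes rose in 8 of 13 and fell in 3 (8 and 3 adjusted over the list alone). Adjusted p was 0.0191, and adjusted p = 0.203 with an estimated correlation.

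Unfolded protein and integrated stress response genes rose in 15 of 26 and fell in 7 in the non-apoptotic fraction (16 and 7 adjusted over the list alone), with the chaperone gene DNAJB9 at 2.12. Adjusted p was 0.0269, and adjusted p = 0.453 with an estimated correlation. Ribosomal protein genes fell in 32 of 40 cases and rose in 3 (33 and 3 adjusted over the list alone). Adjusted p was 6.79e-09, and adjusted p = 0.275 with an estimated correlation. Beside these groups 12 of 13 mitochondrial mRNAs fell (12 adjusted over the list alone), with MT-ND1 at -1.01. Adjusted p was 0.0025, and adjusted p = 0.51 with an estimated correlation. Their share was 1.53% ± 0.127, 1.48% ± 0.148, 1.27% ± 0.0636 and 1.40% ± 0.212 (SD, n = 2) at the 4 times.

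Neither apoptosis list passed in the non-apoptotic fraction. Pro-apoptotic genes rose in 4 of 12 cases and fell in 4 (the same adjusted over the list alone, adjusted p = 0.55), and anti-apoptotic genes rose in 5 of 9 and fell in 2 (5 and 3 adjusted over the list alone, adjusted p = 0.368). Cell-cell adhesion genes rose in 10 of 29 cases and fell in 12 (the same adjusted over the list alone, adjusted p = 0.456), with CDH4 at -1.34. PI3K and AKT pathway genes rose in 8 of 24 and fell in 11 (9 and 12 adjusted over the list alone, adjusted p = 0.51), and AKT1 and AKT2 fell by 0.48 and 0.33. In the mean 10555 genes passed, 5299 higher and 5256 lower, 2529 of them past 2-fold, and the single times gave 7762, 9415, 9766 and 10720. The responses of the lines to suspension, with separation included in Tpm2.1 cells, share no library. They had 3793 genes higher in both (1811 by independence), 4162 lower in both (1690 by independence) and 530 in opposite directions. Across genes, which are not independent replicates, the responses had a Pearson r of 0.65 and a Spearman rho of 0.70.

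**Figure D2:**
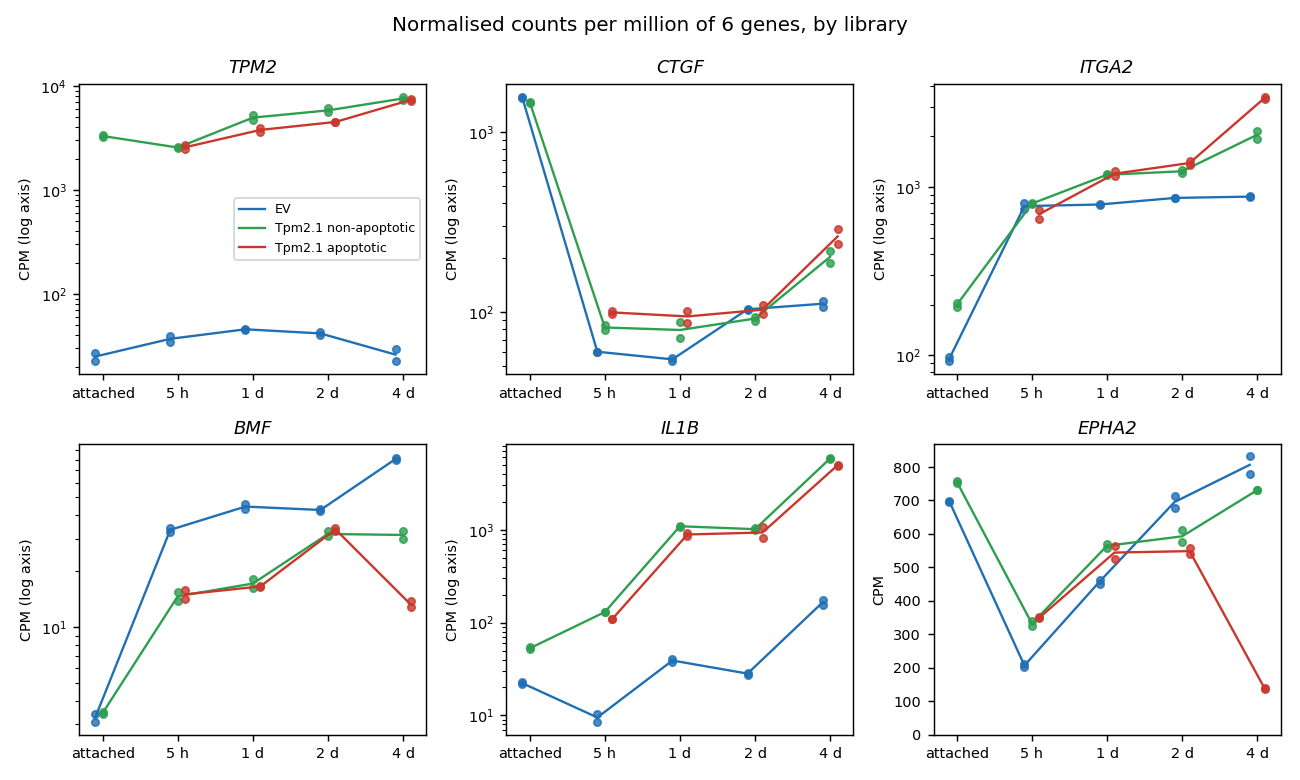
Counts scaled to library size (CPM) of TPM2, CTGF, ITGA2, BMF and IL1B (log axis) and EPHA2 (linear axis) in each library of attached cells and of cells at the 4 times in suspension, with blue for EV, green for Tpm2.1 non-apoptotic cells (attached green points are unseparated) and red for Tpm2.1 apoptotic cells; lines join group means. IL1B reached 5862 CPM in non-apoptotic and 4959 CPM in apoptotic Tpm2.1 cells at 4 days against 165 CPM in EV cells, and EPHA2 stood at 138 CPM in the apoptotic fraction at 4 days. The CPM values are not corrected for GC content.

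Time in suspension was compared as 4 days against 5 hours. In EV cells 9077 genes passed and in the non-apoptotic Tpm2.1 fraction 9444. NF-kB and inflammatory genes rose in 21 of 26 cases in EV cells (median 1.65) and in 24 of 26 in the Tpm2.1 fraction (median 2.02), with 2 falls each; in EV cells the list had 14 falls and a median of -0.53 at 5 hours against attached cells and 18 rises and a median of 1.51 at 4 days. All 30 G2/M genes fell between 5 hours and 4 days in both, with medians of -1.13 in EV and -2.43 in the Tpm2.1 fraction. EPHA2 went from 207 ± 7.70 to 806 ± 37.2 CPM in EV cells and from 332 ± 10.3 to 731 ± 0.99 CPM in the Tpm2.1 fraction (SD, n = 2). These lists were not tested as sets for this contrast.

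The next comparison asked how apoptotic and non-apoptotic Tpm2.1 cells in suspension differed, as the mean of 4 times (8 libraries each). Mitochondrially encoded mRNAs of the respiratory chain were higher in the apoptotic fraction: MT-ND1 (ENSG00000198888, mitochondrial genome, 3307 to 4262) rose by 1.87 ± 0.063 (SE; adjusted p = 2.15e-24), by 1.97, 1.79, 1.49 and 2.24 at the successive times, and MT-ND5 and MT-CYB rose by 1.93 and 1.81. The nuclear-retained RNA MALAT1 rose by 1.43 ± 0.048, by 0.73, 1.01, 1.35 and 2.65 over time. COX6B1, a nuclear-encoded subunit of the same chain, fell by 1.14 ± 0.044, and RPL10 (chromosome X, 154389955 to 154409168), a ribosomal protein gene, fell by 1.11 ± 0.031. Without 4 days COX6B1 and RPL10 fell by 0.43 and 0.27. EPHA2 fell by 0.62 ± 0.026 in the mean, which rested on 4 days: it differed by 0.08 at 5 hours, -0.05 at 1 day and -0.11 at 2 days, none of which passed, and fell by 2.40 ± 0.057 at 4 days, from 731 ± 0.99 to 138 ± 3.51 CPM (SD, n = 2). Without 4 days its mean difference was -0.03 ± 0.03 (adjusted p = 0.473). At 4 days fold changes followed the GC content of genes, as given below, and these EPHA2 values are not corrected for that trend.

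All 13 mitochondrial mRNAs rose between the fractions (13 adjusted over the list alone), with a median of 1.61 (adjusted p = 4.45e-12). Of 9 nuclear-retained RNAs 8 rose (8 adjusted over the list alone, adjusted p = 2.75e-05), while 34 of 40 ribosomal protein genes fell and 2 rose (35 and 2 adjusted over the list alone, adjusted p = 6.13e-13). Each of these lists gave adjusted p = 0.198 with an estimated correlation. Mitochondrial mRNAs took 4.61% ± 1.04, 4.24% ± 0.29, 3.41% ± 1.04 and 6.13% ± 0.382 of counts in the apoptotic fraction at the 4 times (SD, n = 2).

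Metabolic and stress lists were also lower in the apoptotic fraction, in the mean of times. Autophagy and lysosome genes fell in 19 of 26 cases and rose in 2 (20 and 2 adjusted over the list alone), with CTSD at -1.19. Adjusted p was 8.02e-04, and adjusted p = 0.251 with an estimated correlation. Hypoxia and glycolysis genes fell in 22 of 30 and rose in 3 (22 and 4 adjusted over the list alone), with ENO1 at -0.75. Adjusted p was 5.05e-04, and adjusted p = 0.3 with an estimated correlation. NRF2 targets fell in 15 of 21 and rose in 3 (the same adjusted over the list alone), with the ferritin chain FTH1 at -0.89. Adjusted p was 0.0013, and adjusted p = 0.289 with an estimated correlation. Unfolded protein and integrated stress response genes fell in 20 of 26 cases and rose in 2 (the same adjusted over the list alone), with DDIT4 at -0.91. Adjusted p was 7.94e-04, and adjusted p = 0.276 with an estimated correlation. The sizes of these genes rested largely on 4 days: without it CTSD differed by -0.01 (adjusted p = 0.919), and ENO1, FTH1 and DDIT4 fell by 0.25, 0.12 and 0.15. Values without 4 days are adjusted over the 32 lists of that test, here and below, and not over 192 tests. The 4 lists then gave, in this order, adjusted p = 0.0020, 0.0024, 1.60e-04 and 0.0014. They gave adjusted p = 0.305, 0.341, 0.235 and 0.305 with an estimated correlation.

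Cholesterol synthesis genes fell in 18 of 26 cases and rose in 3 between the fractions (the same adjusted over the list alone), with CYP51A1 at -1.35. Adjusted p was 0.0021, and adjusted p = 0.49 with an estimated correlation. Without 4 days CYP51A1 fell by 0.24 and the median of the list went from -0.30 to -0.12, with 12 falls and 1 rise. Adjusted p was then 0.0324, and adjusted p = 0.633 with an estimated correlation. Actin and focal adhesion genes fell in 21 of 35 and rose in 4 (the same adjusted over the list alone), with the actin-severing gene CFL1 at -0.67. Adjusted p was 5.28e-04, and adjusted p = 0.198 with an estimated correlation. The call ended after the GC correction and also without 4 days (15 falls, 8 rises, median -0.08, adjusted p = 0.0813), where CFL1 fell by 0.22. Immediate early genes fell in 16 of 24 and rose in 2 (the same adjusted over the list alone). Adjusted p was 0.0040, and adjusted p = 0.139 with an estimated correlation. This call too ended after the GC correction and without 4 days (2 falls, 1 rise, median -0.02, adjusted p = 0.944).

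Pro-apoptotic genes fell in 8 of 12 cases and rose in 2 in the mean of times (the same adjusted over the list alone), with a median of -0.49. Adjusted p was 0.0185, and adjusted p = 0.119 with an estimated correlation. BAK1 (ENSG00000030110, chromosome 6, 33572547 to 33580293), which permeabilises the outer mitochondrial membrane, fell by 4.08 at 4 days and differed by 0.05 at 5 hours. Without 4 days 2 of the 12 fell, with a median of -0.03 (adjusted p = 0.944). Anti-apoptotic genes rose in 4 of 9 cases and fell in 2 (the same adjusted over the list alone, adjusted p = 0.331), and BMF differed by 0.03, -0.06, 0.08 and -1.24 at the successive times. Eph receptors and ephrins fell in 10 of 17 cases and rose in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.0547), with a median of -0.62, and without 4 days 1 fell and 0 rose. Cell-cell adhesion genes fell in 11 of 29 cases and rose in 7 (the same adjusted over the list alone, adjusted p = 0.449), with NECTIN2 at -0.61, and at -0.08 without 4 days, which did not pass (adjusted p = 0.0822). PI3K and AKT pathway genes fell in 12 of 24 and rose in 8 (the same adjusted over the list alone, adjusted p = 0.841), and without 4 days 3 fell and 3 rose. AKT1 fell by 0.48 in the mean and by 1.72 at 4 days, and its mean difference without 4 days was -0.06 (adjusted p = 0.202). The 4-day values of BAK1, BMF and AKT1 are likewise not corrected for the GC content of the genes.

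Over the 3 earlier times several lists passed between the fractions, none of which held with an estimated correlation (both adjusted over these 32 lists). All 40 ribosomal protein genes fell, with a median of -0.28. Adjusted p was 8.91e-23, and adjusted p = 0.177 with an estimated correlation. All 13 mitochondrial mRNAs rose, with a median of 1.53. Adjusted p was 3.04e-20, and adjusted p = 0.177 with an estimated correlation. Of 16 heat shock genes 14 fell, with a median of -0.25. Adjusted p was 1.45e-07, and adjusted p = 0.235 with an estimated correlation. In the mean of 4 times that median was -0.12 and the list did not pass (adjusted p = 0.0721). G2/M genes fell in 18 of 30 cases and rose in 2, and G1/S genes fell in 17 of 30 and rose in 1. Adjusted p was 5.67e-04 for each, and adjusted p = 0.235 with an estimated correlation. In the mean of 4 times 9973 genes passed, 4404 higher and 5569 lower in the apoptotic fraction, 998 past 2-fold (481 higher and 517 lower). Without 4 days 6612 passed, 2867 higher and 3745 lower, and past 2-fold 538 were higher and 14 lower.

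At single times 3683 genes passed at 5 hours, 3317 at 1 day, 2858 at 2 days and 12390 at 4 days, and 279, 383, 221 and 7164 of them were past 2-fold. The change between 4 days and 5 hours was itself past the threshold for 11506 genes. At 4 days the fold change followed the GC content of the genes: with genes in 10 equal bins of GC content, the median was 0.98 in the lowest bin (23.1 to 38.5%) and -2.79 in the highest (61.4 to 83.9%), and across genes Spearman's rho with GC content was -0.73, against 0.39, 0.06 and -0.05 at the earlier times. A GC correction gave 2254 genes at 5 hours, and at 1 day it lowered the share of called genes that were higher from 41.4% to 26.5%, while a fit of that time's libraries alone raised it to 55.4%. Leaving out 1 library moved the smaller counts by over 1.5 times. Each such removal left a group with 1 library, which by itself lowers power, so a lower count need not reflect the library left out. At 5 hours the count was 1687 without non-apoptotic replicate 1, 2225 without non-apoptotic replicate 2 and 1712 without apoptotic replicate 2. At 1 day it was 1871 without non-apoptotic replicate 1 and 1755 without apoptotic replicate 2, and at 2 days it was 1771 without non-apoptotic replicate 1 and 1125 without apoptotic replicate 1, with 1538 in a fit of that time's libraries alone.

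**Figure D3:**
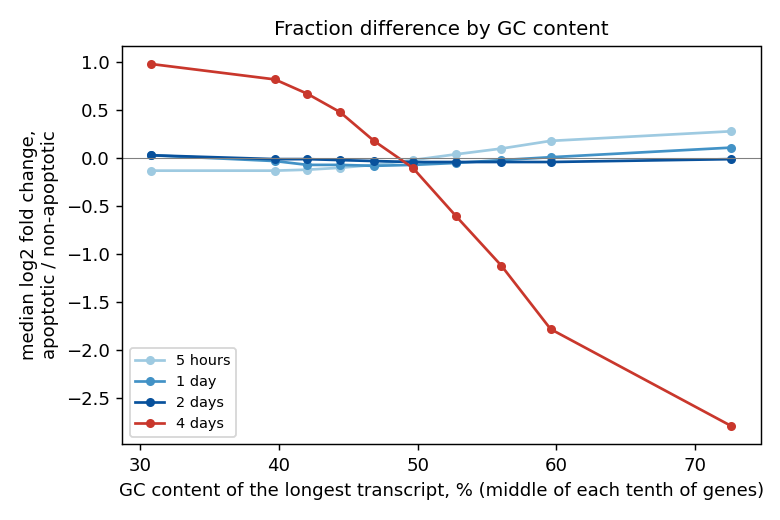
Median log2 fold change of the apoptotic against the non-apoptotic fraction (vertical) in 10 equal bins of gene GC content (horizontal, percent), with a line per time in suspension. The line for 4 days runs from 0.98 to -2.79, the line for 5 hours runs the other way from -0.13 to 0.28, and those for 1 and 2 days stay between -0.08 and 0.11.

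**Figure D4:**
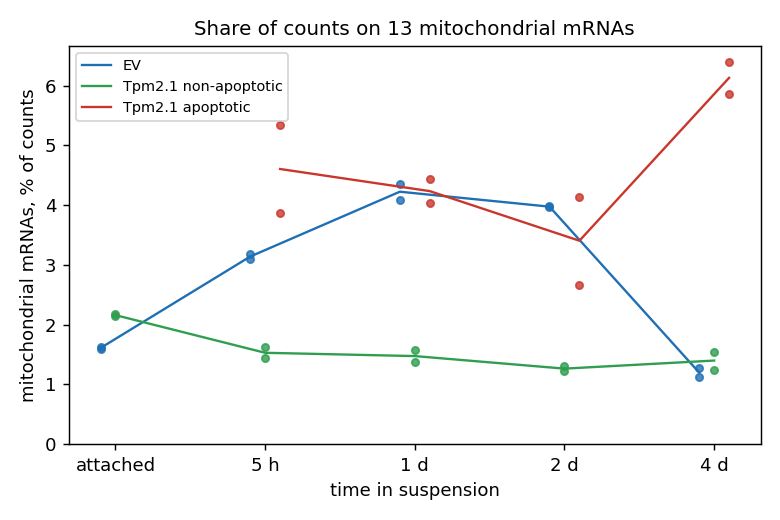
Share of counts on 13 mitochondrial mRNAs (vertical, percent) in attached cells and at 4 times in suspension, with a point per library and lines through group means. The apoptotic fraction lies above the non-apoptotic fraction at every time, and EV cells lie near the apoptotic fraction at 1 and 2 days and near the non-apoptotic fraction at 4 days.

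The lines were then compared in suspension, non-apoptotic Tpm2.1 cells against unseparated EV cells (8 libraries each). MMP1 rose by 6.33 ± 0.044 (SE), IL1B by 4.72 ± 0.046 (adjusted p = 3.20e-43; 3.78, 4.80, 5.17 and 5.15 at the successive times), PTGS2 by 4.12 ± 0.059 and SPP1 by 5.82 ± 0.25. RSAD2, an antiviral gene, lay at or under 0.345 CPM in EV groups and between 13.3 and 19.96 CPM in non-apoptotic groups. TPM2 rose by 7.05 ± 0.049. The activin subunit INHBB fell by 2.75 and ITGA10 by 2.42 ± 0.073. Among apoptosis genes BIRC3 rose by 2.88 ± 0.046, BCL2A1 by 2.64 ± 0.059, MCL1 by 0.92 and the pro-apoptotic PMAIP1 by 1.73 ± 0.039, while BMF fell by 1.09 ± 0.044. EPHA2 rose by 0.15 ± 0.026 in the mean (adjusted p = 2.99e-06), with 0.68 at 5 hours, 0.30 at 1 day, -0.23 at 2 days and -0.14 at 4 days.

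NF-kB and inflammatory genes rose in 25 of 26 cases and fell in 1 (25 and 1 adjusted over the list alone), with a median of 2.40 (adjusted p = 1.20e-19). Interferon-stimulated genes rose in 21 of 30 and fell in 3 (21 and 3 adjusted over the list alone, adjusted p = 5.57e-09), with a median of 0.96 and OASL at 3.49. Immediate early genes rose in 22 of 24 (22 adjusted over the list alone, adjusted p = 6.79e-09), with EGR1 at 1.62 and JUNB at 1.14. Unfolded protein and integrated stress response genes rose in 18 of 26 cases and fell in 3 (the same adjusted over the list alone), with the chaperone HSPA5 at 1.37. Adjusted p was 5.33e-07, and adjusted p = 0.155 with an estimated correlation. Heat shock genes rose in 15 of 16 and fell in 1 (the same adjusted over the list alone), with DNAJB1 at 0.79. Adjusted p was 5.90e-07, and adjusted p = 0.234 with an estimated correlation.

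Mesenchymal genes rose in 9 of 13 and fell in 3 in non-apoptotic Tpm2.1 cells against EV (the same adjusted over the list alone), with ZEB2 at 1.03. Adjusted p was 0.0030, and adjusted p = 0.15 with an estimated correlation. Tropomyosins rose in 3 of 4 cases (the same adjusted over the list alone), with TPM4 at 0.21 beside the overexpressed gene. The list holds TPM2 itself (list median 0.2, mean 1.85), so its call is not independent of the overexpression. Adjusted p was 0.0179, and adjusted p = 0.197 with an estimated correlation. Cholesterol synthesis genes fell in 22 of 26 cases and rose in 2 (the same adjusted over the list alone). Adjusted p was 8.63e-06, and adjusted p = 0.331 with an estimated correlation. NRF2 targets fell in 13 of 21 and rose in 3 (14 and 3 adjusted over the list alone), with the quinone reductase NQO1 at -0.57. Adjusted p was 0.0380, and adjusted p = 0.478 with an estimated correlation; the call ended after the GC correction.

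Cell cycle and ribosomal lists had mostly rises at some times and mostly falls at others between the lines, a change that was not tested for the lists. G2/M genes fell in 22 of 30 cases and rose in 2 in the mean (the same adjusted over the list alone), with 19 rises at 5 hours, 3 rises and 8 falls at 1 day, 18 rises at 2 days and 30 falls at 4 days. Adjusted p was 4.48e-04, and adjusted p = 0.233 with an estimated correlation. G1/S genes fell in 23 of 30 and rose in 3 (the same adjusted over the list alone), with 22 rises at 5 hours and 29 falls at 4 days. Adjusted p was 7.43e-04, and adjusted p = 0.203 with an estimated correlation. Ribosomal protein genes rose in 24 of 40 and fell in 4 in the mean (the same adjusted over the list alone), with a median of 0.09, 34 rises at 2 days and 34 falls at 4 days. Adjusted p was 0.0295, and adjusted p = 0.624 with an estimated correlation. All 13 mitochondrial mRNAs fell in the mean (13 adjusted over the list alone), with medians of -1.13, -1.49, -1.64 and 0.28 at the 4 times. Adjusted p was 4.54e-07, and adjusted p = 0.293 with an estimated correlation. Nuclear-retained RNAs fell in 7 of 9 and rose in 1 (8 and 1 adjusted over the list alone), with MALAT1 at -1.51. Adjusted p was 0.0099, and adjusted p = 0.383 with an estimated correlation.

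Cell-cell adhesion genes rose in 15 of 29 cases and fell in 7 in this comparison (16 and 7 adjusted over the list alone, adjusted p = 0.208), with the desmosome and junction genes JUP at -1.43, PKP3 at -0.90 and DSG2 at 0.44. PI3K and AKT pathway genes rose in 8 of 24 and fell in 14 (the same adjusted over the list alone, adjusted p = 0.449), with PIK3CD at 0.62. AKT1 fell by 0.17, a sign that turned after the GC correction (0.04), and AKT2 fell by 0.44. Anti-apoptotic genes rose in 4 of 9 and fell in 4 (the same adjusted over the list alone, adjusted p = 0.102), with a median of -0.01 and a mean of 0.74. Pro-apoptotic genes rose in 6 of 12 and fell in 5 (the same adjusted over the list alone, adjusted p = 0.52). In the mean 10409 genes passed, 4914 higher and 5495 lower in the Tpm2.1 fraction, 1454 past 2-fold. The single times gave 7024, 6880, 7634 and 7552. After the GC correction the balance in the mean turned, with 5633 higher and 4698 lower.

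The apoptotic fraction against EV asked which line differences both fractions share. TPM2 rose by 6.85 and MMP1 by 6.26 in the apoptotic fraction, near their values in the other fraction, and RSAD2 rose in both from EV levels close to 0. In the mean 11692 genes passed, 5373 higher and 6319 lower, 2365 past 2-fold, and 7731 passed without 4 days. Both fractions were higher than EV for 3400 genes and lower for 3821, and had opposite directions for 1111. These comparisons share the EV libraries: independence gave 1536 and 2020, a simulation with no effect gave 0 in edgeR, and with the EV libraries split between the fractions 2847 were higher and 3175 lower in both. The simulation held no differing genes, so it cannot show how far sharing raises the overlap where many genes differ. Fold changes of the apoptotic fraction against EV followed the GC content of genes (Spearman's rho -0.56 across genes). The overlap was not counted after the GC correction or without 4 days.

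The last comparison tested whether the line difference, Tpm2.1 against EV, changed between attached and suspended cells. Its values are signed, the difference in suspension less that in attached cells, so an upward shift can be a larger rise, a smaller fall or a turn of sign. IL1B shifted by 3.48 ± 0.11 (SE, adjusted p = 1.58e-24), from 1.25 attached to 4.72 in suspension, MMP1 by 2.63 ± 0.083, BCL2A1 by 2.54 ± 0.13 and PMAIP1 by 1.06 ± 0.083. ITGA10 had -3.41 ± 0.31, MALAT1 -2.77 ± 0.11 and BMF -1.17 ± 0.16. Neither TPM2 (0.00) nor EPHA2 (0.04, adjusted p = 0.662) passed, though TPM2 passed without 4 days (-0.38) and EPHA2 after the GC correction (0.16). NF-kB and inflammatory genes shifted upward in 21 of 26 cases and downward in 0 (22 and 0 adjusted over the list alone), with a median of 1.83 (adjusted p = 1.92e-20) and CXCL8 at 2.56.

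Stress and signalling lists shifted as well. Unfolded protein and integrated stress response genes shifted upward in 16 of 26 cases and downward in 3 (the same adjusted over the list alone), with HSPA5 at 0.96. Adjusted p was 2.50e-05, and adjusted p = 0.199 with an estimated correlation. Immediate early genes shifted upward in 12 of 24 and downward in 2 (13 and 3 adjusted over the list alone), with FOS at 1.49. Adjusted p was 0.0061, and adjusted p = 0.15 with an estimated correlation. Autophagy and lysosome genes shifted upward in 14 of 26 and downward in 2 (15 and 2 adjusted over the list alone), from a median of -0.17 attached to 0.03 in suspension, where the list did not pass. Adjusted p was 1.31e-04, and adjusted p = 0.198 with an estimated correlation. Anti-apoptotic genes shifted upward in 4 of 9 cases and downward in 2 (4 and 3 adjusted over the list alone), with MCL1 at 0.87. Adjusted p was 0.0295, and adjusted p = 0.175 with an estimated correlation. PI3K and AKT pathway genes shifted downward in 11 of 24 and upward in 3 (12 and 3 adjusted over the list alone), from a median of 0.10 attached to -0.12 in suspension, neither of which passed, with TSC1 at -0.45. Adjusted p was 0.0302, and adjusted p = 0.251 with an estimated correlation.

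Heat shock, mesenchymal, interferon-stimulated, endothelial and ribosomal lists also passed upward and G2/M genes downward, with adjusted p = 0.0031, 0.0021, 0.0012, 0.0321, 3.05e-07 and 0.0160. In the same order they gave adjusted p = 0.443, 0.139, 0.194, 0.155, 0.32 and 0.37 with an estimated correlation. Mitochondrial mRNAs shifted downward in 13 of 13 cases (13 adjusted over the list alone), with a median of -1.35. Adjusted p was 6.25e-11, and adjusted p = 0.2 with an estimated correlation. Nuclear-retained RNAs shifted downward in 7 of 9 (7 adjusted over the list alone). Adjusted p was 1.29e-05, and adjusted p = 0.198 with an estimated correlation. Cell-cell adhesion genes shifted upward in 8 of 29 and downward in 8 (8 and 9 adjusted over the list alone, adjusted p = 0.716). In all 5764 genes passed, 2917 upward and 2847 downward, 1018 past 2-fold.

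Of 192 list tests 81 passed and 20 held with an estimated correlation. These were the actin, integrin, YAP and TAZ, G2/M and G1/S lists in suspension of either line, NF-kB and inflammatory genes wherever they passed, and endothelial markers in attached cells. Interferon-stimulated genes held between the lines, attached and in suspension, and in suspended Tpm2.1 cells, and immediate early genes held between the lines attached and in suspension.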

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

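The GC test at 4 days and the tests of the separation, of handling on the column and of attached cells were chosen after the result was seen, and the reading of the mitochondrial shares was made stricter after its outcome was known; the thinning of counts and the splits were not. The GC correction was added after the data were seen, and its test on the inflammatory genes was written down before that test's value was seen.

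The difference between suspended and attached cells was not the same in EV and non-apoptotic Tpm2.1 cells, by a test in edgeR, for 5764 genes. This held for IL1B (3.48), MMP1 (2.63), BCL2A1 (2.54), PMAIP1 (1.06), BMF (-1.17), ITGA10 (-3.41) and MALAT1 (-2.77), with a median of 1.83 for NF-kB and inflammatory genes and -1.35 for mitochondrial mRNAs. Only the suspended Tpm2.1 cells were separated, so line and separation cannot be told apart in these values. The difference between the fractions changed between 5 hours and 4 days for 11506 genes, by the same kind of test, 7422 of them past 2-fold. After the GC correction 8154 passed, 3076 past 2-fold; 5467 were called in the same direction as before and 1371 in the opposite one, so much of this result depends on the GC trend.

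At 4 days 7164 genes passed and differed more than 2-fold between the fractions, against 279, 383 and 221 at the earlier times. After the GC correction 3337 genes were past 2-fold, against 185, 370 and 225 earlier, with a remaining rho of -0.09 with GC content. A smooth trend with the GC content of the longest transcript thus fell short as the whole cause. The correction used that transcript only, so it cannot speak to GC effects through other transcripts or parts of a gene. The lower depth of the 4-day apoptotic libraries also fell short, since 6931 genes were past 2-fold with every library thinned to 13043529 counts, against 237, 347 and 193. RNA breakdown in dying cells and a change in which cells bind Annexin V by 4 days both stay open and were not tested. The GC trend may still account for a part of the pattern, as the count fell from 7164 to 3337.

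NF-kB and inflammatory genes were higher in non-apoptotic Tpm2.1 cells than in EV cells in suspension (median 2.40). Removal of Annexin V positive cells from the Tpm2.1 line alone is argued against by the apoptotic fraction, in which the list was also higher than EV (median 2.12, 24 of 26 higher). A trend with the GC content of the longest transcript is argued against by the median of 2.43 after the GC correction. Handling on the column is argued against as the whole cause by the attached cells, which the labels do not describe as separated (median 0.44, 17 of 26 higher). The further 1.83 in suspension cannot be told apart from handling on the column, because every suspended Tpm2.1 library and no EV library was separated. An effect of Tpm2.1 on the response to detachment may account for it, and stays open as a hypothesis.

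Mitochondrial mRNAs were lower in non-apoptotic Tpm2.1 cells than in EV cells in suspension (median -0.94). An effect of the line shared by attached cells is argued against by the attached cells, where the median was 0.38. Removal of Annexin V positive cells from the Tpm2.1 line only would place the share in EV cells between the shares of the fractions. It lay there or within 1 SD of either at 4 of 4 times, but with 2 libraries a group that window is wide. At 2 days EV cells (3.98%) lay above the apoptotic fraction (3.41%), and at 4 days EV cells (1.20%) lay below the non-apoptotic fraction (1.40%). The removal cannot be told apart from a lower share in living Tpm2.1 cells, since EV cells were not separated, and both stay open.

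The grouping in the 3 means over times was set against other splits, a test that cannot exclude chance. Only 30 splits were counted, and splits that mixed the groups added their differences to the spread. Of 30 splits of the 16 libraries within times, 1, the real one, called as many genes for the fractions (9491, against 8607 for the highest other), for non-apoptotic cells against EV (10785 against 8684) and for apoptotic cells against EV (11333 against 9836). For the fractions and for apoptotic cells against EV the high counts among the other splits point to the 4-day libraries: the 7 other splits that parted these as the real one did called 7245 to 8607 for the fractions, the 13 such splits called 5840 to 9836 for apoptotic cells against EV, and splits that mixed these libraries called 0. For non-apoptotic cells against EV the 11 such splits called 0 to 8684, and those that mixed the 4-day libraries at most 975, so these libraries alone do not account for the high counts there.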

How the results depend on the processing

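The GC correction, the scaling of the FPKM table, means without 4 days and list tests after the GC correction were chosen after the data were seen. All 26 counts of passing genes stayed within 1.5 times under DESeq2, its size factors, FPKM scaling, no filter, protein-coding genes and the replicate block, as did 25 under the GC correction, 24 with the libraries of a contrast alone and 161 of 172 with a library left out. The exceptions were the fractions at 5 hours under the GC correction (2254 against 3683), and, with the libraries of a contrast alone, the lines in attached cells (5440 against 3516) and the fractions at 2 days (1538 against 2858). Their causes were not tested. The spread between the 2 libraries of a group was uneven, by the chi-square of counts per degree of freedom for genes with at least 20 counts over both. It was 2.19 in attached EV and 2.09 in attached Tpm2.1 cells. At 2 days it was 5.2 in the non-apoptotic and 8.93 in the apoptotic fraction. A spread pooled over groups can make p values too small for groups that vary more and too large for those that vary less. Leaving out 1 library gave 2028 to 2188 for the lines in attached cells, and 1687 to 2773, 1755 to 2391 and 1125 to 3129 for the fractions at 5 hours, 1 day and 2 days. Without 4 days the means of the fractions and of apoptotic cells against EV gave 6612 and 7731 against 9973 and 11692; these are the 2 means that hold the 4-day apoptotic libraries, and the other 4 stayed within 1.5 times. Similar counts hid other genes under the GC correction: of 12390 between the fractions at 4 days 6441 were called in the same direction and 1739 in the opposite one, and opposite calls numbered 573 for the mean of the fractions, 940 for apoptotic and 121 for non-apoptotic cells against EV. Mitochondrial mRNAs took larger shares of the FPKM sums in all 14 groups, as in attached EV (6.58%) and Tpm2.1 cells (8.68%) and up to 22.1% in the apoptotic fraction at 4 days.

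Named genes kept direction and side of the threshold in 505 cases under DESeq2 (1 newly passed, 5 no longer passed), 499 under the GC correction and 6445 with a library left out. Under the GC correction TPM2 and AKT2 went to 0.02 and 0.16 between the fractions and AKT1 to 0.04 in non-apoptotic cells against EV; the cause was not tested. The result BOLA2B: EV suspension vs adherent, mean of times, for a gene with near-identical copies, ranged from -5.14 (without EV_adherent replicate 2) to 0.06 (without EV_adherent replicate 1). Without 4 days 12 genes changed sign between the fractions, 1 of them not named here (-0.04) and the others AKT2 (0.23), BCAR1 (0.01), FLNA (0.06), IER5 (0.06), JUNB (0.04), PKP3 (0.04), AKT1S1 (0.03), BAX (0.02), BAD (0.05), CEBPB (0.06) and MVD (0.05), since their mean rested on 4 days.

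Of 192 list tests 81 passed with the preset correlation, 20 with an estimated one, 80 with the replicate block and 84 after the GC correction, 77 of them shared. In fry, which asks whether a list moves on balance and not against other genes, 158 passed; the pro-apoptotic list in suspended EV cells went up in fry (adjusted p = 2.31e-07) and down in camera.

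With the replicate block the lines in attached cells gave 3494 genes and the mean of the fractions 9959, and a block within each time gave 9450 for that mean. No pairing by replicate number was seen: over 91 pairs of groups the correlation of replicate differences was -0.075 to 0.054, with 0 over 0.1. Counting noise in low-count genes lowers such correlations, so a pairing cannot be excluded. Genes well below the filter, such as CDH1 and CDH2, were out of reach. In attached cells, with 2 libraries a side, 92.5% of simulated 1.5-fold changes in well-counted genes were called, and depth was not varied there.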

Other observations

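Extracellular matrix genes rose in 14 of 27 cases and fell in 8 in non-apoptotic Tpm2.1 cells against EV cells in suspension (the same adjusted over the list alone; adjusted p = 0.0223, and adjusted p = 0.274 with an estimated correlation). The laminin chain LAMB1 rose by 1.92 and the collagen chain COL6A3 by 2.83. Of the 5 endothelial markers tested, out of 10 listed, 3 rose and 1 fell (the same adjusted over the list alone). Adjusted p was 0.0292, and adjusted p = 0.15 with an estimated correlation. TIE1 rose by 5.18 ± 0.055 (SE), from group means of 2.15 to 5.24 CPM in EV to 87.3 to 177 CPM in non-apoptotic cells, and KDR, the main receptor for VEGFA, rose by 1.66, while PECAM1 fell by 0.54. Eph receptors and ephrins rose in 7 of 17 cases and fell in 3 (the same adjusted over the list alone; adjusted p = 0.0845). EPHA3 lay at or under 0.031 CPM in EV groups and at 1.57 to 1.97 CPM in non-apoptotic groups, EPHB2 rose by 0.58 and EPHB4 fell by 0.45.

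Several lists passed in none of the 6 main comparisons. Of 19 p53 targets 8 rose and 4 fell in suspended EV cells and 7 rose and 5 fell in non-apoptotic Tpm2.1 cells (8 and 4, and 7 and 6, adjusted over the list alone), and 12 fell and 3 rose in apoptotic against non-apoptotic cells (the same adjusted over the list alone; adjusted p = 0.199), while without 4 days 1 fell and 2 rose. Death receptor and caspase genes rose in 12 of 24 cases and fell in 6 in non-apoptotic suspended Tpm2.1 cells (13 and 6 adjusted over the list alone; adjusted p = 0.122). Of the markers of other cell types, 10 fibroblast and 12 leukocyte markers were listed, but only 5 and 2 passed the count filter and were tested. Of those tested, 4 of 5 fibroblast and 2 of 2 leukocyte markers rose in suspended EV cells (4 and 2 adjusted over the list alone, adjusted p = 0.0901 and 0.362). As many rose in non-apoptotic suspended Tpm2.1 cells (4 and 2 adjusted over the list alone, adjusted p = 0.0646 and 0.277). Luminal breast markers rose in 3 of 12 cases and fell in 4 in suspended EV cells (the same adjusted over the list alone; adjusted p = 0.68).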
